A study of Bos taurus
Mus musculus and Bos taurus and Mus musculus with 5 samples.

How the data were processed

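Heterokaryons of bovine fetal fibroblasts and C57BL mouse embryonic stem cells were sampled 24, 48 and 72 h after fusion, with unfused cells of each kind as controls. Per the labels' protocols, fibroblasts came from 1 fetus and were grown at 38.5 °C, and stem cells were grown at 37 °C on irradiated mouse feeder fibroblasts with 1 µM PD0325901, which inhibits the kinase MEK, and 3 µM CHIR99021, which inhibits GSK3. The cells were co-cultured for 4 h, fused with polyethylene glycol for 2 min and kept afterwards at 37 °C in stem cell medium without these inhibitors, so heterokaryons differed from the bFF control in medium, temperature and company as well as in fusion. From the mESC control they differed in the inhibitors and in company as well as in fusion. For each library 200 cells were isolated by imaging and sorting, and cDNA was made from polyadenylated RNA with the SMART-Seq v4 kit and 14 cycles.

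The authors deposited 2 tables, of bovine and of mouse RefSeq transcripts, with whole read counts per transcript and library and the same values as RPM. Per the file headers the count columns are reads, and the deposited RPM equalled each count scaled by its column's total, so RPM was checked against the counts and printed values were computed from the counts. The builds bosTau8, GRCm38 and mm10 are named in the submitters' processing notes. The aligner, the counter and the rule that told the species apart are not given in the sources used here. The files give transcript starts counted from 0, and starts are printed counted from 1. The value 1 never occurs in either table, so a 0 may stand for a single read. A row of column totals in the mouse table was left out. No mitochondrially encoded transcripts were listed. Gene names changed into spreadsheet dates, 23 bovine and 60 mouse, were restored by RefSeq number for 23 and 57. Transcripts were summed by gene name, 14234 bovine transcripts to 13923 genes and 35814 mouse transcripts to 24543 genes, since the tables list isoforms of 1 gene separately. Counting by strand is not stated, so overlapping genes and near-identical copies are uncertain.

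Each library stands alone in its group. The heterokaryon libraries carry 1 treatment label, and the main test set these 3 against the 1 control of the species with edgeR 4.0.16 (quasi-likelihood test, TMM scaling, genes at 10 CPM or more in at least 1 library, Benjamini-Hochberg adjusted p under 0.05) in R 4.3.3. With no replicate cultures, its p-values describe the spread between libraries of different times. DESeq2 1.42.0 was the alternative, and its missing adjusted p-values (344 mouse genes) stayed missing. Values by time were compared by size only, at least 4-fold on log2(CPM + 1) with 10 CPM or more in 1 of the libraries. Folds against 0 reads were computed against a floor of 3 reads, without the counting error of the heterokaryon reads. Lower 95% counting limits are printed beside them. Intervals are at 95% and cover counting error only. On simulated data with 200 changed genes, the bovine test recovered 75% of 4-fold and 95% of 16-fold changes and called 17 unchanged genes of 7078, and the mouse test recovered 91% and 100% and called 9 of 8497. The simulated control was given the spread of the heterokaryon libraries, so these rates hold only if the real control varies like them.

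Wrong assignment between species was estimated per gene as the reads of the other species' control, scaled by that species' reads in the heterokaryon library. The estimate assumes that each gene of the other species kept its control level. A share can therefore exceed 100% where that gene fell, and wrong assignment can be missed where it rose. Before the data were examined, the groups, tests, alternatives and 28 gene lists were fixed, and so was the rule for named genes: POU5F1, SOX2 and NANOG, the 4 members of each list with the largest mean change at 10 CPM or more, the 8 highest and 8 lowest genes by their smallest change over the 3 times at 50 CPM or more, and the 4 highest and 4 lowest between 24 and 72 h with 48 h in between. Other members of these lists, the genes called in both species and the comparison genes COL1A1 and VIM were named after their values were seen. Not every gene that the rule takes is reported here. List medians were compared with 10000 random lists of the same size matched on expression in 20 bins. Simulated unchanged groups, 100 in number, gave the chance values for comparisons that share a control. Their spread was taken from the 3 heterokaryon libraries, differences in time included. Alternatives were other scalings, pseudocounts, filters and fold limits, leaving out each heterokaryon library, and, added after the data were seen, subtraction of the estimated wrongly assigned reads and removal of orthologs where they exceed 10%. Tables were handled in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.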

Results

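Transcripts were counted in heterokaryons, cells that hold the nuclei of 2 fused cells side by side, made from bovine fetal fibroblasts (bFF) and mouse embryonic stem cells (mESC) with polyethylene glycol. Because the parents were of different species, reads could be assigned to the species of the nucleus they came from, with an estimated error given below. The share of reads left unassigned is not known here. Heterokaryons were sorted 24, 48 and 72 h after fusion, and unfused bFF and mESC served as controls, with 1 library of 200 cells for each of the 5 groups. The bovine table held 2634269 reads for bFF and 982769, 1331989 and 1541793 reads for the 24, 48 and 72 h heterokaryons. The mouse table held 3446461 reads for mESC and 2427089, 1731084 and 1836299 reads for the same heterokaryons. There were no replicate libraries of any group, so values by time carry a counting interval only, and reads amplified by PCR are not independent molecules.

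The first question was how much of the heterokaryon RNA came from each nucleus. Bovine transcripts made up 28.8% of the assigned reads at 24 h (95% exact binomial interval 28.77 to 28.87), 43.5% at 48 h (43.43 to 43.54) and 45.6% at 72 h (45.59 to 45.69). Both tables also list the control of the other species, which measures wrong assignment. In the mESC library 1.74% of reads were listed as bovine, led by MAP2K3 with 5102 reads, and in the bFF library 1.81% were listed as mouse, led by the ribosomal precursor Rn45s with 18934 reads. Scaled to each heterokaryon library, such reads would make up 4.38%, 2.30% and 2.11% of the bovine reads at 24, 48 and 72 h, and 0.745%, 1.42% and 1.55% of the mouse reads.

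The central question was whether the fibroblast nucleus expressed pluripotency genes after fusion. Bovine POU5F1, which encodes the pluripotency factor OCT4 (chromosome 23, plus strand, start 27769893 in bosTau8), had 0 reads in bFF, 23 reads at 24 h, 3 at 48 h and 6 at 72 h. This was 23.4 RPM, reads scaled to the bovine total of the library, at 24 h (95% Poisson interval 14.8 to 35.1), 2.25 at 48 h (0.464 to 6.58) and 3.89 at 72 h (1.43 to 8.47). For the 0 reads in bFF the upper limit of this interval was 1.40 RPM, and the floor of 3 reads was 1.14 RPM. The 24 h level was 20.5-fold that floor, and the lower 95% counting limit of the fold over bFF was 15.4. Across the 3 heterokaryon libraries POU5F1 did not pass the edgeR test (adjusted p = 0.0969), and it passed with DESeq2 (adjusted p = 0.0469) and without the 72 h library (edgeR adjusted p = 0.0248), while the other alternatives gave up to 0.121. Bovine SOX2 had 0 reads in all 4 of these libraries, with a 95% Poisson upper limit of 3.75 RPM at 24 h, and NANOG had 2 reads in bFF and 0 in the heterokaryons, so neither was detectable at this depth.

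**Figure D1:**
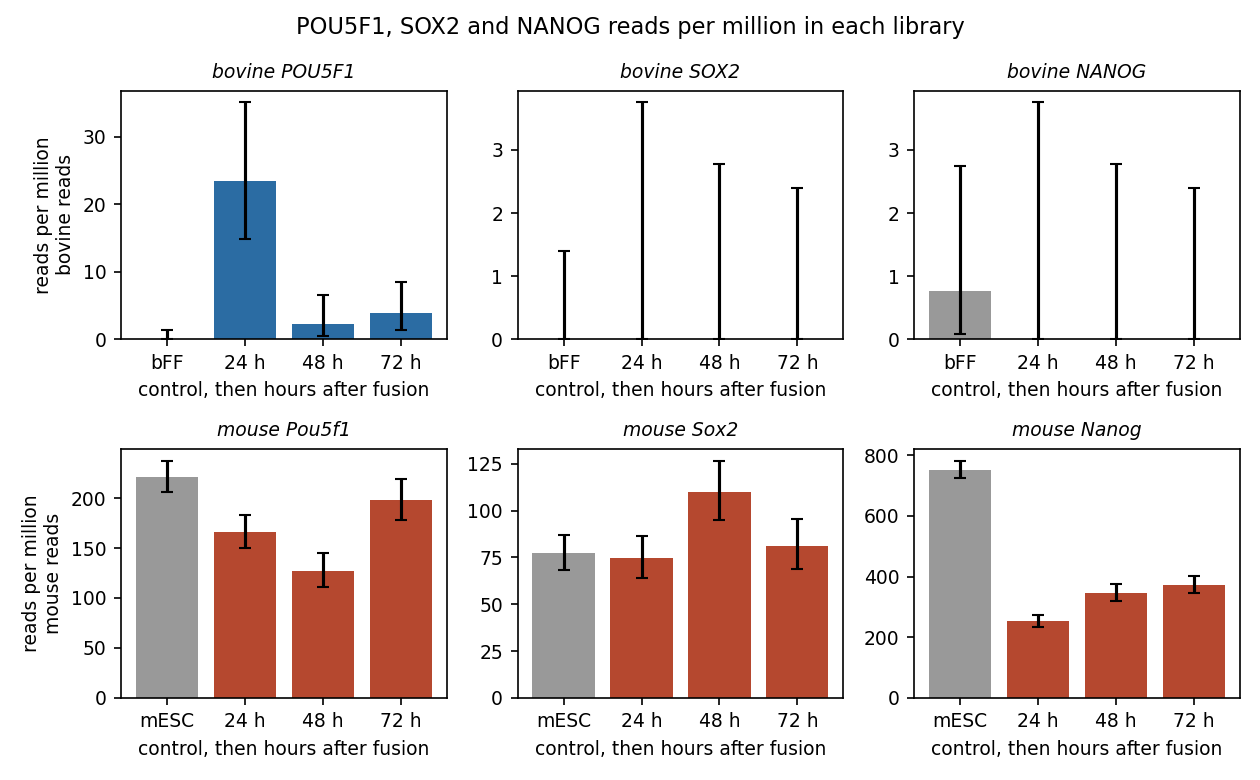
RPM (reads scaled to the species total of the library) for bovine POU5F1, SOX2 and NANOG (top, blue) and mouse Pou5f1, Sox2 and Nanog (bottom, red) in the unfused control (grey) and in heterokaryons by hours after fusion. Bars are 1 library each and lines are 95% Poisson intervals. Bovine POU5F1 stood at 23.4 at 24 h against 0 in bFF, and mouse Nanog fell from 752 in mESC to 253 at 24 h.

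Of the pluripotency list, 6 genes with POU5F1 among them could be tested in bovine transcripts and 3 rose, while 4 passed adjusted over the list alone. CD9, a membrane tetraspanin, rose by a log2 fold change of 2.02 ± 0.46 (SE, 3 heterokaryon libraries against 1 control; edgeR adjusted p = 0.0162). TDH (2.04 ± 0.48) and TFCP2L1 (0 reads in bFF and 10, 18 and 18 in heterokaryons) also passed, but wrongly assigned mouse reads would account for 60.4% of the TDH reads and 162% of the TFCP2L1 reads at 24 h. With such reads subtracted bovine TDH did not pass (log2 fold change 0.97). Reads were found for 16 of 26 listed genes, and their median was 0.36 (log2) over the 3 times, at percentile 84.3 among random lists matched on expression. It was 0 at 24 h (percentile 69.5), 0 at 48 h (74.8) and 0.86 at 72 h (99.93), the last set by genes with few reads, 7 of FBXO15 and 2 each of NR5A2 and SALL1. The median over the 3 times was 1.94 for the 6 members at 10 CPM or more, a filter that POU5F1 and TFCP2L1 reached in heterokaryons alone, and wrongly assigned reads weigh on TDH and TFCP2L1 among them.

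Compared with bFF, bovine transcripts in heterokaryons showed higher glycolytic and cell cycle genes and lower sterol synthesis and fibroblast matrix genes. NDUFA4L2, a mitochondrial protein induced by low oxygen, rose from 6 reads in bFF to 485, 1478 and 1641 (log2 fold change 8.69 ± 0.79, edgeR adjusted p = 6.3e-05). The urokinase receptor gene PLAUR rose by 5.30 ± 0.43 and uridine phosphorylase UPP1 by 6.28 ± 0.52. ANKRD37, the lactate transporter gene SLC16A3 and the globin gene HBA had 0 reads in bFF and at 24 h were 91.9-fold, 38.4-fold and 80.3-fold the floor of 3 reads. The lower 95% counting limits of these folds were 73.4, 29.9 and 64.0. The cell cycle inhibitor CDKN1C fell from 814 reads to 4, 4 and 3 (log2 fold change -6.60 ± 0.38, where wrong assignment would give 52.8% of the 24 h reads), somatostatin SST from 4771 to 29, 58 and 51 (-5.56 ± 0.31) and the chemokine CXCL10 from 407 to 3, 0 and 3 (-6.45 ± 0.55).

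By gene list, 15 of 17 tested glycolysis genes rose and 0 fell, with SLC2A3 at 4.90 ± 0.50, PGK1 at 3.18 ± 0.42 and LDHA at 2.19 ± 0.37 (log2 fold change ± SE), and 15 passed adjusted over the list alone. Of 26 tested proliferation genes 12 rose and 0 fell (18 and 0 adjusted over the list alone), among them the ribonucleotide reductase gene RRM2 (3.50 ± 0.50), the replication helicase gene MCM5 (3.52 ± 0.51) and the mitotic kinase gene BUB1 (3.42 ± 0.58). Of 16 tested cholesterol synthesis genes 11 fell and 0 rose (12 and 0 adjusted over the list alone), including MSMO1 (-2.75 ± 0.30), IDI1 (-2.75 ± 0.30) and HMGCS1 (-2.55 ± 0.43), and 7 passed with DESeq2. Of 38 tested fibroblast and matrix genes 9 fell, such as the growth factor receptor gene PDGFRA (-2.63 ± 0.28), FAP (-1.86 ± 0.29) and COL3A1 (-1.41 ± 0.33), and 3 rose, among them TGFBI (6.37 ± 0.70) and MGP (2.96 ± 0.85); 11 fell and 5 rose adjusted over the list alone. COL1A1 (-0.52 ± 0.29, edgeR adjusted p = 0.307) and VIM (-0.14 ± 0.38, edgeR adjusted p = 0.870) did not pass.

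Smaller lists moved in part. Among 8 tested epithelial genes the keratin genes KRT18 (-2.68 ± 0.42), KRT8 (-1.50 ± 0.32) and KRT19 (-1.36 ± 0.33) fell and the desmosomal cadherin gene DSG2 rose (2.55 ± 0.54), with 4 fallen and 1 risen adjusted over the list alone. Among 5 tested WNT targets TCF7 and NKD1 rose from 0 reads in bFF, and 4 rose adjusted over the list alone. At 24 h TCF7 was 58.0-fold the floor of 3 reads, and the lower counting limit of this fold was 45.8. Of 12 tested ERK targets IER3 rose (4.40 ± 0.40) while SPRY1 (-2.73 ± 0.57) and EGR1 (-2.01 ± 0.41) fell, with 3 and 5 adjusted over the list alone. Of 11 tested interferon response genes CXCL10, IFIT3 (-3.34 ± 0.61) and IRF9 (-2.52 ± 0.61) fell and 5 fell adjusted over the list alone. Of 23 tested stress genes DDIT4 rose (3.70 ± 0.43) and EGR1 and DDIT3 (-1.20 ± 0.27) fell, with 2 risen and 3 fallen adjusted over the list alone. Of 10 senescence secretory genes 2 rose, among them IL6 (5.01 ± 0.57), and IGFBP7 fell (-1.28 ± 0.34), with 2 and 2 adjusted over the list alone. Of 10 mesenchymal transition genes CDH11 (-1.61 ± 0.27) and TGFBR2 (-1.48 ± 0.43) fell, also adjusted over the list alone. Over the 3 times, list medians (log2) were -1.17 for ERK targets (percentile 0.02 among matched random lists) and 1.52 for WNT targets (100). The medians were -0.51 for stress genes (0.14), -0.63 for interferon response genes (2.01) and 0.62 for senescence secretory genes (98.85). Epithelial and mesenchymal transition medians were 0.42 (89.2) and -0.03 (52.25). By time the senescence secretory median was 0.20 at 24 h (77.49), 0.18 at 48 h (75.39) and -0.26 at 72 h (11.21). At each single time it lay inside the central range of matched random lists.

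In the p53 list GADD45B (3.17 ± 0.54), PLK2 (1.66 ± 0.34) and BAX rose of 13 tested, and in the DNA methylation list GADD45B and MBD3 rose of 8; 84.2% of the BAX and 39.3% of the MBD3 reads at 24 h would be wrongly assigned mouse reads. The same held for 88.7% of the reads of MTF2, the 1 polycomb or trithorax gene of 8 that passed. With such reads subtracted, bovine BAX (log2 fold change 0.71) and bovine MBD3 (log2 fold change 0.92) did not pass and bovine MTF2 turned to -0.29. Adjusted over the list alone 3 rose and 2 fell in the p53 list, 3 rose in the DNA methylation list and 1 in the polycomb and trithorax list. Of markers of other tissues, HBA (blood), MYF5 (muscle, 2 reads in bFF and 10.7-fold at 24 h, counting interval 2.14 to 103), TUBB3 (2.27 ± 0.46, neural) and NES (1.35 ± 0.39, germ layers) rose and ACTC1 (-3.55 ± 0.48, muscle) fell, with the same counts adjusted over the list alone. In 8 lists members were tested and 0 passed edgeR (contractile, ribosomal, respiratory chain, primed, trophoblast, totipotent-like, germline and endothelial). Of their 178 tested entries 16 had an unadjusted edgeR p under 0.05, against 1776 of all 7376 tested bovine genes. In these lists 3 entries passed DESeq2, and 1 trophoblast gene fell adjusted over the list alone. Of these lists, the ribosomal median over the 3 times lay below the central 95% of matched random lists (0.08, percentile 1.79, and below 0 with library totals alone). At single times medians outside that range were -0.57 at 24 h and 0.74 at 72 h for the contractile list, 1.75 at 24 h for the endothelial list, 0.39 at 48 h for the respiratory chain and -0.09 at 72 h for the ribosomal list.

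Over all genes, 322 bovine genes rose and 352 fell of 7376 tested (edgeR, adjusted p under 0.05), each in the same direction at all 3 times, and in 58 of the former and 13 of the latter wrongly assigned reads would exceed 10%. The spread in this test comes from heterokaryon libraries that differ in time, and the lone control was assumed to vary like them. Without the 24 h library 830 rose and 919 fell, and without the 48 h library 223 fell, whereas DESeq2 gave 347 higher and 184 lower and a filter of 50 CPM left 211 lower.

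**Figure D2:**
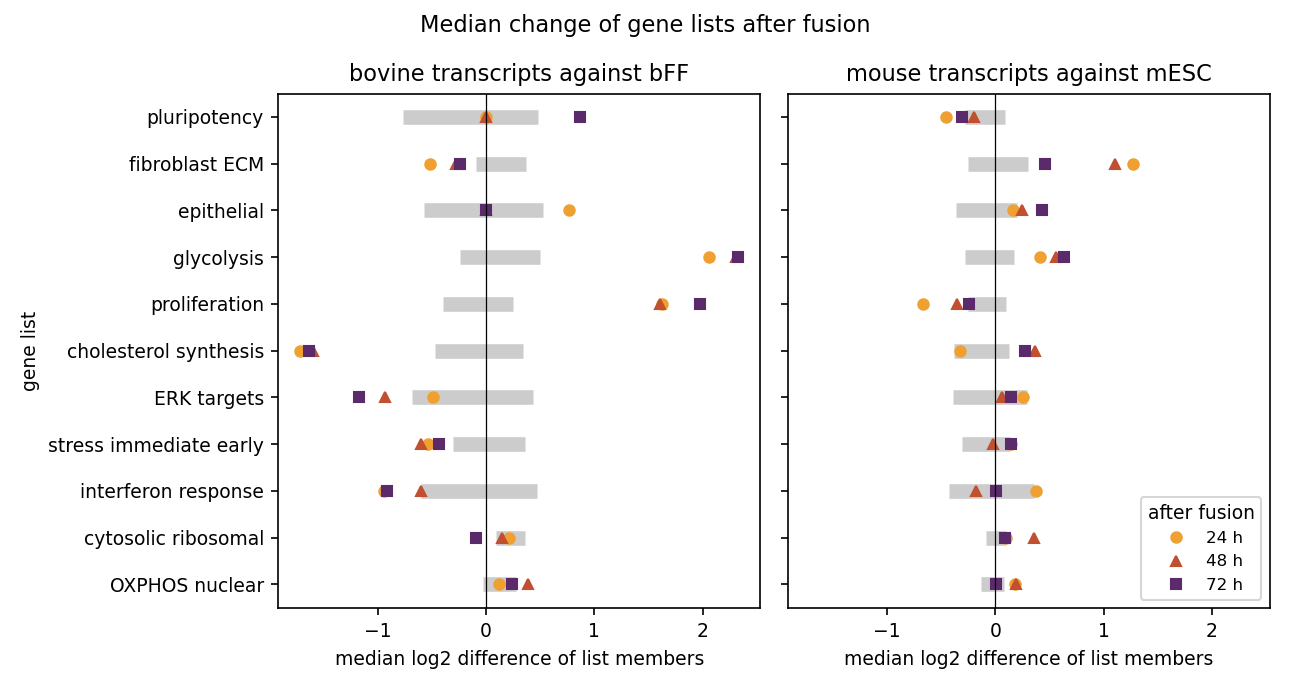
Median log2 difference of the members of 11 gene lists between heterokaryons and the unfused control, for bovine transcripts (left) and mouse transcripts (right), at 24 h (circles), 48 h (triangles) and 72 h (squares). Grey bars hold the central 95% of 10000 random lists matched on expression, for the mean of the 3 times. The bovine glycolysis median was 2.21 and the cholesterol synthesis median -1.69 over the 3 times.

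At single times, 284 bovine genes were at least 4-fold higher and 204 lower than in bFF at 24 h, 207 and 246 at 48 h, and 234 and 290 at 72 h, with no replicate check. Over genes with 10 CPM in any library, 506, 478 and 548 differed this much, against 121, 109 and 105 on average in simulated unchanged groups. Scaling by library totals alone gave 170 and 297 at 48 h and 184 and 363 at 72 h, with the median of all genes shifted to -0.20 (log2) at both times. At all 3 times 116 genes were at least 4-fold higher and 74 lower. These comparisons share the bFF library, so part of the overlap can come from it: simulated unchanged groups against it gave on average 5.79 and 4.03 such genes. Independent lists of the genes past this fold at each time, with 10 CPM in any library, would share 0.299 and 0.3003.

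The mouse comparison asked what happened to the stem cell nucleus. The mESC control was grown with PD0325901 and CHIR99021, and heterokaryons were kept without them after fusion. An effect of fusion therefore cannot be told apart from loss of these inhibitors in the mouse transcripts. Nanog, a core pluripotency factor gene (chromosome 6), fell from 2591 reads in mESC to 613, 599 and 684 (log2 fold change -1.26 ± 0.21, edgeR adjusted p = 0.0075). The nuclear receptor gene Nr0b1 (-1.71 ± 0.37), the threonine dehydrogenase gene Tdh (-1.48 ± 0.18) and Klf2 (-1.39 ± 0.20) also fell. Pou5f1 (-0.48 ± 0.24, edgeR adjusted p = 0.337) and Sox2 (0.15 ± 0.29, edgeR adjusted p = 0.821) did not pass. In all, 4 of 33 tested pluripotency genes fell and 0 rose, and 8 fell and 1 rose adjusted over the list alone. The list median was -0.46 at 24 h (percentile 0.12 among matched random lists), -0.19 at 48 h (18.955) and -0.31 at 72 h (0.25). Over the 3 times it was -0.24 (5.17).

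Some epithelial and stress genes rose in the mouse transcripts. Krt18 (2.92 ± 0.41), Krt19 (3.03 ± 0.59) and the tight junction gene Cldn6 (1.77 ± 0.39) rose among 19 tested epithelial genes, with 4 risen and 1 fallen adjusted over the list alone. Of 22 tested stress genes Jun (3.72 ± 0.64), Fos (2.26 ± 0.25), Fosb (2.84 ± 0.60) and Egr1 (1.93 ± 0.36) rose and Asns fell (edgeR adjusted p = 0.0144), with 5 and 2 adjusted over the list alone. Fos, Egr1 and Ier3 (2.61 ± 0.47) also made up the 3 of 11 ERK targets that rose, against 4 adjusted over the list alone. Outside the lists Anxa3 (3 reads in mESC, 65.6-fold at 24 h, counting interval 22.0 to 322), Anxa2 (2.91 ± 0.35) and Ndrg1 (2.57 ± 0.37) rose, and the cation channel gene Trpm1 (-3.54 ± 0.49), Accsl (-2.54 ± 0.35) and Epop (-1.73 ± 0.26) fell.

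Of 18 tested mouse glycolysis genes 6 rose and 0 fell, including Slc2a1 (1.43 ± 0.22), Hk2 (1.43 ± 0.24) and Tpi1 (1.04 ± 0.17), and 12 rose adjusted over the list alone. Of 30 tested proliferation genes Plk1 fell (-1.07 ± 0.22), and 8 fell adjusted over the list alone, with a list median of -0.44 at percentile 0. Of 13 tested fibroblast and matrix genes S100a6 (5.10 ± 1.15), Cyr61 (2.30 ± 0.49), Col1a1 and Prrx1 rose, and 7 rose adjusted over the list alone and 2 passed with DESeq2, but at 24 h wrongly assigned bovine reads would make up 85.8% of the Col1a1 reads and 200% of the Prrx1 reads. For the mesenchymal cadherin gene Cdh11, which rose among 3 tested transition genes (1 adjusted over the list alone), that share was 238%. The estimates for Prrx1 and Cdh11 are too high, since bovine PRRX1 and CDH11 at 24 h were 0.22-fold and 0.35-fold their bFF levels. The call for mouse S100a6 was lost with DESeq2 (adjusted p = 0.138), a filter of 50 CPM (edgeR adjusted p = 0.0980) or wrongly assigned reads subtracted (0.0577), and the other alternatives gave 0.0470 or less. In 19 lists members were tested and 0 passed edgeR, among them cholesterol synthesis, p53, WNT targets, interferon response and all markers of other tissues. Of their 289 tested entries 44 had an unadjusted edgeR p under 0.05, against 1455 of all 8857 tested mouse genes, and 6 passed DESeq2. Adjusted over the list alone, 5 contractile genes rose and 1 fell, 2 and 1 in the DNA methylation list, 1 and 1 in the p53 list, and 1 rose in the senescence and in the cholesterol lists, while 1 fell in each of the polycomb, interferon, germline and endothelial lists. Over the 3 times, 7 of these lists had medians above the central 95% of matched random lists: contractile (0.60), p53 (0.55), germ layers (0.47), DNA methylation (0.32), ribosomal (0.19), cholesterol synthesis (0.17) and respiratory chain (0.15). By time, the cholesterol synthesis median was -0.33 at 24 h and 0.36 and 0.28 later, the p53 median 0.99, 0.27 and 0.11, and the germ layer median 0 at 24 h and inside that range at each time. Outside that range at single times were also the senescence list at 24 h (1.46) and the polycomb list at 72 h (0.35).

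Over all genes, 51 mouse genes rose and 36 fell of 8857 tested (edgeR, adjusted p under 0.05), and in 6 of those that rose wrongly assigned reads would exceed 10%. Without the 24 h library 222 rose and 258 fell, without the 72 h library 181 and 233, and without the 48 h library 16 fell. DESeq2 gave 90 higher and 29 lower, DESeq2 size factors in edgeR 78 higher, no filter 97 and 70, and a filter of 50 CPM 27 and 22.

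At single times 143 mouse genes were at least 4-fold higher and 32 lower than in mESC at 24 h, 48 and 31 at 48 h, and 35 and 7 at 72 h. Genes at least 4-fold higher at all 3 times numbered 25, against 1.27 on average in simulated unchanged groups sharing the control and 0.00463 for independent lists. Lower at all 3 times were 2, a count inside the simulated range (1.26 on average and at most 5). The median of all mouse genes lay at -0.11 (log2) at 48 h and -0.11 at 72 h. Over genes with 10 CPM in any library, 186 differed at least 4-fold at 24 h and 93 at 48 h, against 37.9 and 45.5 on average in the simulations. At 72 h 54 such genes did, against 44.4 on average and at most 61 in 100 simulations. The simulated spread holds the differences in time between heterokaryon libraries. A count inside the simulated range therefore does not show that nothing changed.

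Within heterokaryons, the bovine chemokine gene CCL2 was highest at 24 h with 2497 reads and stood at 522 and 12 reads at 48 and 72 h, against 214 in bFF. GRO1, another chemokine gene, had 290, 17 and 8 reads, and the imprinted noncoding RNA gene H19 had 233, 50 and 7 reads against 1203 in bFF. GZMA, a granzyme gene, went from 0 reads at 24 h to 21 and 143, and PLBD1 from 56 to 450 and 878. In mouse transcripts the epidermal genes Krtdap (432, 25 and 11 reads) and Dmkn (286, 37 and 6) and the keratin gene Krt17 (230, 34 and 16) were highest at 24 h, while Nr0b1 (82, 116 and 192) and Cdx1 (61, 74 and 136) were lowest then. Between 24 and 72 h, 66 bovine genes were at least 4-fold higher and 138 lower at 72 h (47 and 183 by library totals alone), and 17 mouse genes were higher and 83 lower.

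The last comparison asked whether both nuclei changed alike, over genes with the same symbol. Of 5635 genes tested in both species, 12 rose in both, against 1.60 expected from lists of these sizes (one-sided Fisher's exact test across genes, p = 2.48e-08). They were ANKRD37, BHLHE40, BNIP3, ENO1, FAM162A, IER3, LDHA, NDRG1, NDUFA4L2, PGK1, SLC2A1 and TPI1, which include glucose transport and glycolysis genes. For bovine NDRG1 up to 15.97% of the reads would be wrongly assigned. APOE, GNPDA1, PROS1 and SGK1 fell in both, 4 genes against 0.869 expected (one-sided Fisher's exact p = 0.0100). Fisher's test treats genes as independent, and the calls of both species rest on the same heterokaryon libraries, each species against a lone control. These p-values therefore measure no spread between cultures. Opposite calls numbered 7. No expected count was computed for these, so whether agreement exceeded disagreement relative to chance was not tested. KRT18, KRT19 and EGR1 fell in bovine and rose in mouse transcripts, and CKB and MYBL2 rose in bovine and fell in mouse. CDH11 rose in mouse and TDH in bovine transcripts, each against a fall in the other species. The expected wrongly assigned shares at 24 h were 27.4% for bovine MYBL2, 238% for mouse CDH11 and 60.4% for bovine TDH.

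**Figure D3:**
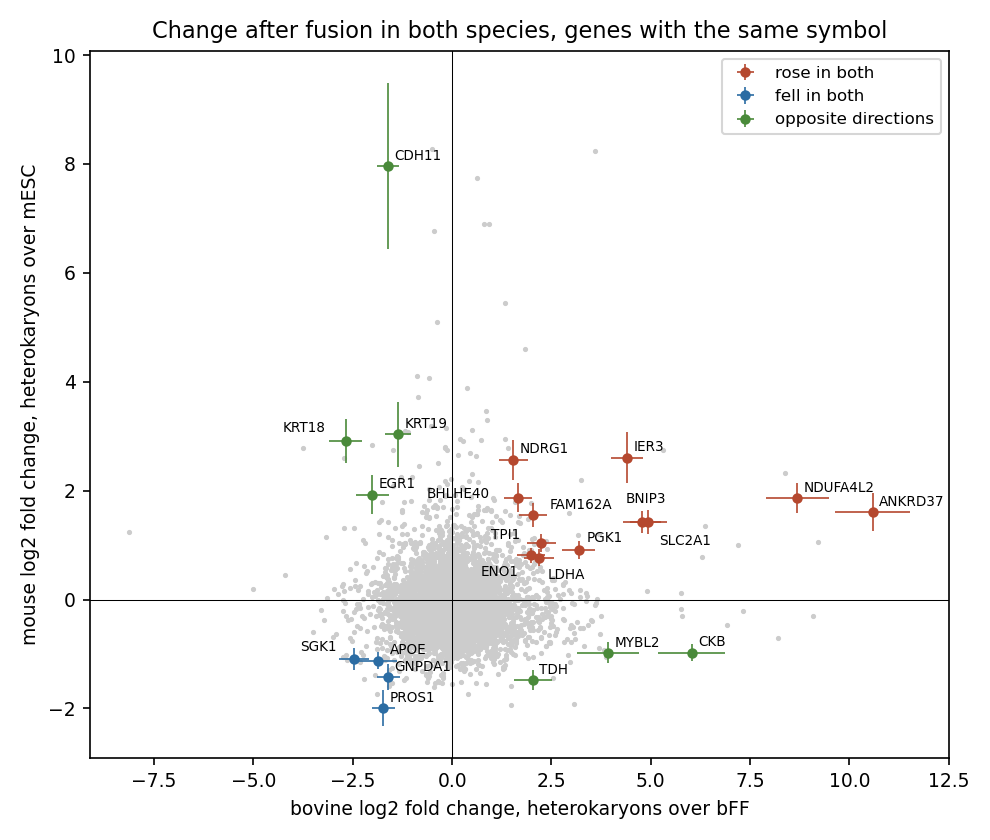
Log2 fold change of 5635 genes in bovine transcripts (horizontal axis, heterokaryons over bFF) and mouse transcripts (vertical axis, heterokaryons over mESC). Grey points are single genes, and coloured points with standard errors passed the edgeR test in both species: 12 rose in both (red), 4 fell in both (blue) and 7 moved in opposite directions (green). ANKRD37 (bovine) and CDH11 (mouse) had 0 control reads, so their fitted sizes are no bound.

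Across all 5635 genes the changes were close to uncorrelated, with Spearman's correlations of 0.012 at 24 h, 0.034 at 48 h and -0.0017 at 72 h. Spearman's correlation between bovine levels and mouse levels in mESC was 0.527 in bFF (95% bootstrap interval 0.505 to 0.547) and 0.593 (0.574 to 0.612), 0.575 (0.554 to 0.595) and 0.584 (0.565 to 0.604) at 24, 48 and 72 h. The intervals cover the choice of genes and not the spread between libraries, which also differed in depth, so no difference between bFF and heterokaryons is shown by them. Genes are not independent replicates, and without genes whose wrongly assigned share exceeds 10% the values were 0.533 in bFF and 0.600, 0.577 and 0.584 in heterokaryons.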

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

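The tests of wrong assignment and sampling depth for POU5F1, the 3 tests of the mouse genes at 24 h and the split of the oxygen list were chosen only after the result was seen, and the oxygen list was drawn up after higher genes of this kind had been seen, as 1 of 2 such lists.

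The median of the fibroblast and matrix list was lower in bovine and higher in mouse transcripts at all 3 times, a difference of -1.2922 (log2, bovine minus mouse, mean of the times), and the proliferation list moved the other way, a difference of 2.1572. Neither difference was tested. Wrongly assigned bovine reads may raise the mouse side of the former, since they would make up 85.8% of the Col1a1 and 200% of the Prrx1 reads at 24 h. The mouse median of the fibroblast and matrix list, 0.65, was 0.33 with 5 CPM added and 1.24 over members at 10 CPM or more. In the controls, 1.7411% of the mESC library and 1.8071% of the bFF library were listed under the other species, a signal outside the main measurement.

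Bovine POU5F1 had 23, 3 and 6 reads in heterokaryons and 0 in bFF. If mouse Pou5f1 reads had been assigned to the bovine gene, the mESC library would hold about 43.5 bovine POU5F1 reads at the 24 h ratio, and it held 0, which argues against this source. At the 24 h rate the bFF library would hold 61.7 reads, and it held 0, so shallow sampling of bFF does not account for the difference either. No library of unfused bovine cells kept beside mES cells was analysed here (0 libraries), so expression started by the medium or the co-culture cannot be told apart from an effect of fusion.

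Genes that respond to low oxygen were higher in both species. A list of such genes was compared with matched random lists, and it held LDHA and TPI1, which had been called higher in both species. The lower of the 2 species' percentiles was 100, with medians of 1.15 (bovine, 10 of 28 tested genes rose) and 0.56 (mouse, 3 of 29). The median estimated share of wrongly assigned reads was 0% in both species. For LDHA and TPI1, with reads in both controls, the largest share was 0.169%. This argues against wrong assignment as the whole cause for these genes only. The estimate can miss reads from genes that rose from a low control level, such as bovine PFKFB3 (0 reads in bFF, 32 at 24 h). For such members wrong assignment stays open. The smallest excess of the list over all genes under 3 scalings was 0.672 (log2). A scaling factor shifts the list and all genes nearly alike, so these scalings were no separate test. Most of the calls on the oxygen list came from 8 members that are also on the glycolysis list, whose rise was known. Without them the medians were 0.64 (bovine, percentile 99.97, 3 of 20 rose) and 0.49 (mouse, percentile 100, 1 of 21). A shared response to low oxygen in the fused cells is a candidate explanation, and cell density or medium stays open, because unfused cells of the same wells were not analysed here.

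Mouse genes at least 4-fold higher at 24 h numbered 143. The median estimated share of wrongly assigned bovine reads among them was 0%, with 4 genes above 50%. This argues against that source for the set only as far as the bovine genes kept their bFF level. Reads from bovine genes that rose can be missed. Feeder fibroblasts in the sorted cells would bring collagen reads, and the ratio of Col1a2 and Col3a1 to Vim in bFF, taken as a stand-in, was 348 times the highest that 0 collagen reads beside 354 of Vim allow at 24 h. Both collagen genes had 0 mouse reads in every library, mESC from feeder culture included, so the test lacks a library that shows them and feeder carry-over stays open. Loss of PD0325901, which blocks the pathway upstream of ERK, stays open too, since the ERK target list stood at percentile 88.92 among matched random lists, inside their central 95%.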

How the results depend on the processing

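No paired analysis was possible because each group has 1 library. Subtraction of wrongly assigned reads and removal of orthologs with over 10% of them were chosen after the data were seen. Depth limits low genes, since 3 reads in the 24 h heterokaryons are 3.05 bovine RPM. The cause of the shifts below was not tested, except that a stricter filter tests fewer genes, a lower fold limit admits more, and a higher pseudocount shrinks the changes of low genes.

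For genes called by edgeR against 322 higher and 352 lower bovine and 51 higher and 36 lower mouse genes, DESeq2 gave 184 bovine lower and 90 mouse higher, DESeq2 size factors gave 78 mouse higher, no filter gave 97 and 70 mouse, and 50 CPM gave 211 bovine lower and 27 and 22 mouse. Leaving out 1 heterokaryon library gave 229 to 830 bovine higher, 223 to 919 bovine lower, 50 to 222 mouse higher and 16 to 258 mouse lower. All other alternatives for these counts stayed within 1.5 times. Among genes at least 4-fold different at 24, 48 and 72 h (bovine 488, 453 and 524, mouse 175, 79 and 42), a pseudocount of 5 CPM gave 216, 241 and 289 bovine and 70, 18 and 10 mouse, 1 CPM as filter gave 847, 750 and 801 and 401, 289 and 235, 50 CPM gave 206, 186 and 241 and 63, 14 and 8, and a 2-fold limit gave 1988, 1842 and 1962 and 1356, 1010 and 687. A pseudocount of 0.1 CPM gave 68 mouse genes at 72 h. Between 24 and 72 h, 204 bovine and 100 mouse genes became 71 and 31 with 5 CPM added and 57 and 25 with the 50 CPM filter. The bovine share of reads was 27.9%, 41.5% and 43.0% without the 100 most abundant genes and 31.3%, 46.3% and 48.5% over shared symbols. List medians moved to 1.94 for bovine pluripotency and 1.24 for mouse fibroblast genes over members at 10 CPM or more, and to 0.33 for the latter with 5 CPM added. With the 50 CPM filter, ortholog changes correlated at 0.078 and 0.098 at 24 and 48 h, and levels at 0.428 in bFF and 0.506, 0.481 and 0.489 in heterokaryons.

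Of genes named by the rule, these log2 fold changes turned sign. With wrongly assigned reads subtracted, MTF2 was -0.29, Agbl5 -0.057 and Cd68 0.0086. Leaving out 1 heterokaryon library gave -1.06 (without 72 h) to 1.33 for CHST9, -0.037 (without 48 h) to 0.31 for Sox2, -0.97 to 0.25 for Lefty2 (0.11 without 48 h), -0.83 to 0.16 (without 24 h) for Krt7, -0.37 to 0.23 (without 24 h) for Tdrd12, -0.19 to 0.11 (without 24 h) for Egfl7, -0.27 to 0.13 for Cd68 (0.096 without 48 h), -0.31 to 0.061 (without 48 h) for Des and -0.86 to 0.22 (without 24 h) for Fxyd6, and Snai1 was 0.16 without 48 h and 0.36 without 72 h. With DESeq2 Egfl7 was 0.022 and Cd68 0.085, with DESeq2 size factors Cd68 was 0.038, and with library totals 0.029. Of these, MTF2 and Agbl5 had passed the main test. Elsewhere among single genes and smaller lists, 1774 values kept direction and call, 119 gained a call, 53 lost it and 25 moved beyond their error.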

Other observations

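The test of imprinted genes was chosen after low values of CDKN1C, H19, MEST and DCN had been seen, on a list that is 1 of 2 drawn up after seeing the data, and these 4 genes were left out of it.

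Some genes of secreted immune signals differed between times in the bovine transcripts, with 1 library per time, and others did so less. They were not tested as a group. CXCL8, a neutrophil chemokine gene, had 12 reads in bFF and 204, 7 and 10 in heterokaryons (45.5-fold at 24 h, 95% counting interval 25.5 to 89.5), while GRO1 had 20 reads in bFF and 290, 17 and 8. IL6 (9 reads in bFF and 96, 106 and 208) and CXCL10 (407 reads in bFF and 3, 0 and 3) differed less than 4-fold between 24 and 72 h. Mouse Ccl2 had 0 reads in mESC and 88, 18 and 0 in heterokaryons. The class II histocompatibility gene BLA-DQB had 2 reads in bFF and 122, 124 and 239 in heterokaryons (163-fold at 24 h, interval 44.2 to 1363). HBA had 90, 89 and 75 reads in heterokaryons, with 0 in bFF and 0 in the mESC library. MYF5 had 2 reads in bFF and 8, 17 and 60 in heterokaryons.

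A hypothesis was that imprinted genes, expressed from 1 parental copy, were lower as a group in the bovine transcripts. Over 22 further imprinted genes with reads the median log2 difference was -0.75, at percentile 0.04 among matched random lists, whose central 95% ran from -0.49 to 0.35. Random lists draw genes singly, so members of a shared locus, such as SNRPN and SNURF, can make this percentile too extreme. Neighbours of the genes left out, such as IGF2 beside H19, were kept. The list is therefore not fully separate from the values that prompted it. With edgeR 1 of 18 tested members passed, IGF2R (-1.54 ± 0.36, adjusted p = 0.0195), and 0 rose. IGF2 had 3439 reads in bFF and 799, 390 and 209 in heterokaryons (edgeR adjusted p = 0.101), and the log2 differences of DIRAS3 and GRB10 were 0.08 and 0.22; these 3 genes were named after their values were seen. The values are in line with a lower level of the group, seen in 1 library per time, and no technical explanation of it was tested.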
